A study of Homo sapiens with 6 samples.

How the data were processed

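The samples were 3 control and 3 LPS-exposed cultures of pancreatic cancer-associated fibroblasts, grouped by their titles. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into strand-specific libraries and sequenced in pairs, with a stated read length of 75 bases. Per the submitters' processing notes, Salmon, DESeq2 and GRCh38 were named, with no version or role. The annotation release is not given in the sources used here.

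The table analysed is a deposited map of text identifiers (transcript, gene and gene name), per the file headers. It holds no count, normalised value or other measurement, and 0 columns of per-sample values were used. The differential expression and gene list tests planned before the data were examined need such values and were not run. The planned fallback, a description of the map, was used instead. Depth and its precision are therefore unknown for all 6 libraries, and the replicates could not be compared.

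Transcripts were counted per gene identifier with pandas 2.3.3. Gene types, positions and the comparison of releases come from GENCODE release 29 on GRCh38. That is the build named in the submitters' notes, but it is not necessarily the release behind the map: 92.1% of the map's gene identifiers and 79.5% of its transcripts were in it. A symbol not in the map was looked up through its gene identifier in GENCODE release 29. The 225 genes of 16 lists were fixed before the data were examined. The genes named in the report are the 2 with most and the 2 with fewest transcripts in each list, ties broken alphabetically, plus MYD88, TLR4, LY96, CD14, IL6, CXCL12 and ACTA2, 68 genes in all, of which 1 is not reported here. PCBP1-AS1, DDX58 and the genes named in the closing section were chosen after their values were seen. The counting was tested on a simulated map with known answers. Alternatives were counting by symbol (by identifier where there was no symbol), dropping version suffixes, and keeping only genes with a symbol.

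For the closing section, only GENCODE release 29 transcripts that the map assigns to the same gene identifier were used. Every stretch of 75 bases was taken from those of each listed gene and searched on the same strand in those of all other genes. The map assigns 198095 transcripts to the same gene identifier as that release. The sequence file used here held no entry for 59 of them, and the other 198036 were searched.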

Results

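The series profiled cancer-associated fibroblasts, a stromal cell type of the tumour, grown in culture from surgical specimens of pancreatic ductal adenocarcinoma. Bulk RNA sequencing was carried out on 3 control libraries and 3 libraries from cells exposed for 24 hours to lipopolysaccharide (LPS) at 100 ng/ml. LPS is a component of the outer membrane of Gram-negative bacteria and is recognised by the receptor TLR4, which signals through the adaptor MYD88. The comparison implied by the design is LPS against control, and the question it addresses is which genes of these fibroblasts respond to LPS.

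That comparison was not analysed here, because no value measured in any of the 6 libraries was at hand. The processed table that was analysed pairs each transcript with its gene and has 3 columns, of which 0 hold a number and 0 are named for a sample. Accordingly, no expression level, fold change, replicate spread, sequencing depth or test is given for any gene, and whether LPS altered IL6, CXCL12, ACTA2 or any other gene remains unanswered. The values below count annotated transcripts. They describe the gene models onto which transcript estimates can be summed, and they carry no information on expression in either group.

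The table listed 254129 transcripts under 63140 gene identifiers, with a mean of 4.02 transcripts per gene and a median of 1. A single transcript was listed for 39366 genes, which is 62.3% of them. The gene with most transcripts was the long non-coding RNA PCBP1-AS1, with 296. Among the 19855 genes that GENCODE release 29 types as protein-coding, the median was 6 transcripts and 14.2% had a single one. Among the 38271 genes that release gives other types, the median was 1 and 85.9% had a single one. The 5014 gene identifiers outside that release are in neither group. These are complete counts over an annotation, so no sampling error attaches to them and no test was applied.

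MYD88, TLR4, LY96 and CD14, which take part in LPS recognition and signalling, were each listed in the table. MYD88 (ENSG00000172936), the adaptor of most Toll-like receptors, had 15 annotated transcripts and lies on the plus strand of chromosome 3 from 38138478 to 38143022. TLR4 (ENSG00000136869) had 4 and lies on the plus strand of chromosome 9 from 117704175 to 117724730. LY96 (ENSG00000154589), which encodes the TLR4 co-receptor MD-2, had 2 and lies on the plus strand of chromosome 8 from 73991352 to 74029087. CD14 (ENSG00000170458), which transfers LPS to that complex, had 4 and lies on the minus strand of chromosome 5 from 140631728 to 140633701. Genes commonly used to describe fibroblast states were also present. IL6 (ENSG00000136244), an inflammatory cytokine, had 9 transcripts and lies on the plus strand of chromosome 7 from 22725884 to 22732002. CXCL12 (ENSG00000107562), a chemokine, had 7 and lies on the minus strand of chromosome 10 from 44370165 to 44386493. ACTA2 (ENSG00000107796), smooth muscle actin, had 13 and lies on the minus strand of chromosome 10 from 88935074 to 88991339. All positions are those of the whole gene in GENCODE release 29 on GRCh38, whereas the transcript counts are those of the table. That release lists 13 transcripts for MYD88, 5 for TLR4, 2 for LY96 and 5 for CD14. It lists 9 for IL6, 8 for CXCL12 and 6 for ACTA2.

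Across 16 gene lists covering inflammatory signalling, fibroblast states, matrix, antigen presentation, proliferation and other cell types, all 225 distinct genes were found. Of these, 224 were found by their symbol. The other, DDX58, a cytosolic RNA sensor, appeared under its current symbol RIGI with 13 transcripts. The median over the 225 genes was 8 transcripts, the highest value was 50, and 20 genes had a single one. These counts and those below belong to the table's annotation. For some of the genes GENCODE release 29 lists fewer transcripts, and for others more.

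In the list of inflammatory cytokines and chemokines, the median was 3 transcripts over 20 genes. CCL8 and CSF2 had 1 each, whereas CSF3 and IL6 had 9 each. Among 22 genes of NF-κB feedback and Toll-like receptor signalling, the median was 6.5, from 1 for the kinase IRAK2 and 2 for LY96 to 21 for the inhibitor NFKBIA and 25 for NFKB1. Interferon-stimulated genes had a median of 12 over 26 genes. The chemokines CXCL9 and CXCL10 had 1 transcript each, MX1 had 48 and the transcription factor IRF1 had 50. In GENCODE release 29, CXCL9 and CXCL10 also have 1 each, but MX1 has 18 and IRF1 has 11. In the list of 11 complement and acute-phase genes, the median was 16, with 1 for PTX3, 5 for SAA1 and 28 for C3.

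Among the fibroblast lists, the 18 genes of the inflammatory state had a median of 5 transcripts. DPT and the hyaluronan synthase HAS2 had 1 each, C3 had 28 and LMNA had 45. The 16 genes of the myofibroblastic state had a median of 10, with 1 for CCN2, 2 for MYL9, 15 for HOPX and 44 for the tropomyosin TPM1. The 11 genes of the antigen-presenting state had a median of 8, with 1 for SLPI, 2 for HLA-DRA, 12 for CD74 and 20 for CIITA, the activator of MHC class II transcription. The 15 genes of MHC class I presentation had a median of 11, from 3 for HLA-E and 5 for PSMB10 to 26 for TAPBP and 29 for NLRC5. Collagens and other matrix genes, 18 in number, had a median of 10.5, from 3 for LUM and 4 for COL5A2 to 27 for FN1 and 35 for ELN. The 14 genes of matrix remodelling had a median of 3.5, with 1 each for MMP9 and MMP12, 8 for MMP14 and 16 for PLAUR. The 18 proliferation genes had a median of 7.5, with 1 each for CCNA2 and E2F1, 17 for RRM2 and 28 for MCM4.

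The lists for other cell types, which cultures grown from a tumour could hold, were likewise complete in the table, and their presence there says nothing of the cells. Epithelial genes had a median of 8.5 transcripts over 10 genes, with 5 for CLDN4, 6 for EPCAM, 18 for KRT8 and 26 for MUC1. Macrophage genes had a median of 9 over 11 genes, with 3 each for FCER1G and LYZ, 13 for C1QB and 23 for PTPRC. Endothelial genes had a median of 6.5 over 8 genes, with 4 each for CLDN5 and KDR and 9 each for PECAM1 and VWF. Pericyte genes had a median of 6 over 7 genes, with 1 for CSPG4, 5 for HIGD1B, 17 for MCAM and 20 for ABCC9. Lymphocyte genes had a median of 6 over 7 genes, with 2 for CD2, 3 for CD79A, 10 for IL7R and 12 for MS4A1.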

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

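No paired analysis was possible because the table holds no values per sample; for the same reason the alternatives planned for LPS against control (normalization, tool, low-count filter, pseudocount, replicates left out) and for the gene list tests were not run. For the transcript counts, dropping version suffixes changed nothing, since no identifier carried one and none was repeated. The share of genes with 1 transcript was 62.3%, against 61.1% when genes were counted by symbol and 51.8% when only genes with a symbol were kept. Both alternatives count a different set of genes. The number of genes was 63140 by identifier, 61510 by symbol (41040 symbols plus the 20470 identifiers without one, each counted by its identifier) and 42670 identifiers with a symbol, all within 1.5 times of each other, the mean was 4.02, 4.13 and 5.22 transcripts, and the median was 1 in each.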

Other observations

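The search for shared sequence was chosen after the table was seen, and the genes named here were chosen after their values were seen. Some genes of the fixed lists share long stretches of sequence with other genes of the same annotation, which bears on how reads of 75 bases can be assigned to them. Positions of those other genes were not compared, except for the pairs of listed genes given below. For the rest, overlapping genes at the same locus were not separated from similar genes elsewhere. Of the 224 listed genes searched, 168 shared no stretch of that length on the same strand with another gene, 9 shared more than 10% of their stretches and 1 shared more than 50%. The search covered 198036 of the 254129 transcripts in the table, so stretches shared through the others were not seen. SOD2 was not searched, since its gene identifier in the table is outside GENCODE release 29. CD68, a marker of macrophages, shared 70.6% of its 2328 distinct stretches with 1 other gene, ENSG00000264772, which has no symbol in the table. CLEC3B, in the inflammatory fibroblast list, shared 45.8% with EXOSC7. The complement gene CFB shared 39.7% with ENSG00000244255. TAP2, a subunit of the peptide transporter of MHC class I presentation, shared 33.8% with ENSG00000250264. PSMB10 shared 23.5% with ENSG00000261884, and CIITA shared 10.8% with ENSG00000280153. PDGFRA, a fibroblast receptor, shared 14.7% with ENSG00000282278.

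The acute-phase genes SAA1 and SAA2 shared sequence: SAA1 shared 35.0% of its stretches with SAA2, and SAA2 shared 13.6% with SAA1. Their positions on chromosome 11 do not overlap, from 18266174 to 18269977 for SAA1 and from 18239223 to 18248643 for SAA2. The chemokine CXCL2 shared 6.87% with CXCL3, and CXCL3 shared 4.57% with CXCL2. On chromosome 4, CXCL2 lies from 74097035 to 74099293 and CXCL3 from 74036589 to 74038807, again without overlap. TLR4 shared 7.96% with ENSG00000285082. These are shares of annotated sequence, not of reads, and read pairs span more sequence than 75 bases.

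A symbol did not always name 1 gene. The table held 488 symbols that stand for more than 1 gene identifier, 2118 identifiers in all, among them 758 for Y_RNA, 170 for Metazoa_SRP and 50 for U3, which are small non-coding RNAs present in many copies. Another 20470 gene identifiers had no symbol. Against GENCODE release 29, 5014 gene identifiers and 52015 transcripts of the table were outside that release. Of the 58126 shared gene identifiers, 6684 had more transcripts in the table and 3299 had fewer. In the table, 4019 shared transcripts stood under another gene identifier than in that release.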
